A study of Homo sapiens with 24 samples.

How the data were processed

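Gene expression was measured in BT-474 cells on 24 Affymetrix HG-U133 Plus 2.0 arrays after biotin labelling by in vitro transcription from the 3' end. The deposited values were log2 levels, 1 per probe set and array, that the authors had made by RMA, which includes quantile normalisation at the probe level. The version of the software and its background step were not given in the sources used here, and the scale was checked on the values. No other column of per-sample values was used here. For arrays, depth is their number, which limits the precision.

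The arrays were grouped by siRNA (HER2 or control), treatment (10 nM estrogen, or vehicle of 0.001% ethanol) and time (4 or 24 h), which gave 8 groups of 3. The labels disagreed for HER2 siRNA estrogen 4 h replicate 3. Its source name gives 24 h while its title, description and characteristics give 4 h, and it was placed at 4 h. The labels carry a running number, and 3 arrays of replicate 1 are numbered apart from the other 21. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays.

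Of 54675 probe sets, 41091 had 1 gene symbol, 1801 had several, 11721 were unnamed in the annotation used and 62 were controls. Symbols were brought up to date through Entrez identifiers. For each of 19775 genes the probe set with the highest mean was used, and a gene was tested if its log2 level was at least 5 in at least 3 arrays, which left 14335. A model with 1 mean per group was fitted across all 24 arrays with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation (prior degrees of freedom 4.92, total 20.9). P-values were adjusted by Benjamini and Hochberg within each comparison, and the threshold was an adjusted p of 0.05. Tables and figures were made in R and Python 3.11.15.

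There were 14 comparisons. They were HER2 siRNA against control siRNA averaged over the 4 conditions and in each of them, estrogen against vehicle within each siRNA and time, the difference of estrogen effects between siRNAs at each time, the differences of the siRNA effect and of the estrogen effect between times, and 24 h against 4 h in control siRNA with vehicle. The relation of the siRNA effect to the estrogen effect across genes was computed at each time, with a reference of 100 simulations of unchanged genes.

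The lists fixed in advance covered nucleotide synthesis, DNA replication, E2F and pocket proteins, mitosis, G1 to S cyclins and inhibitors, DNA repair by recombination, estrogen-induced genes, the HER family and its ligands, MAPK pathway output, FOXO-induced genes, neighbours of ERBB2 on its chromosome, nuclear receptor coregulators, interferon response, cholesterol and fatty acid synthesis, hypoxia and glycolysis, ATF4 and the unfolded protein response, ribosome biogenesis, luminal epithelial genes, basal and mesenchymal genes, and markers of fibroblasts, leukocytes and endothelial cells. Of their 438 entries 372 were tested, 34 were below the filter and 32 had no probe set of their own. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's members move one way on balance. Counts of list members were also made with p adjusted over the list alone.

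The genes named follow a rule. For the averaged siRNA effect, the estrogen effects with control siRNA and the differences of estrogen effects between siRNAs, it took up to 10 genes with the largest difference each way among those past the threshold. Outside the differences of effects, it also asked that the arrays of both groups did not overlap in at least 1 condition. It added ERBB2 and up to 4 members of each list with the smallest adjusted p. For other comparisons it took up to 5 genes each way, and fewer are printed. The lists, the rule, the comparisons and the alternatives were chosen before the data were examined, except for additions made after values were seen. These were 24 h against 4 h in the other 3 conditions and the GAPDH 3' to 5' difference of each array as a covariate. A reference that permuted estrogen and vehicle labels within siRNA 99 times for the relation across genes was another. So was a list of aryl hydrocarbon receptor target genes, drawn up once CYP1A1, CYP1A2, CYP1B1 and TIPARP had been seen.

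The alternatives were no filter or a stricter one (log2 level of 7, 9287 genes), the replicate number as a block, alone or with the number series, leaving out the 3 arrays numbered apart, the mean of a gene's probe sets or every probe set on its own, only the groups compared in the fit, equal medians, quantile normalisation, array weights, an intensity trend with a robust prior, and leaving out each array in turn. Whether equal replicate numbers pair arrays was checked on correlations of deviations from group means. All 3 pairs were over 0.1 in 4 of 9 comparisons of 2 groups, and over all groups 60 of 84 pairs were (median 0.205, against -0.107 for pairs with different numbers). For 23 of 24 arrays the closest array of another group had the same number. The main fit, fixed in advance, leaves the replicate number out, and the block is given as an alternative. The estimated correlation of the list tests also came from the fit without the block, so it may hold a replicate effect. Whether list calls that ended with it would stand with the block was not tested.

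On simulated data with the same design, changes of 1.5, 2 and 4-fold were recovered in the right direction for 100%, 100% and 100% of genes for the averaged siRNA effect, 80.6%, 95.5% and 100% for estrogen with control siRNA at 24 h, and 46.3%, 92.5% and 100% for the difference of estrogen effects at 24 h. Unchanged genes made up 5.66%, 3.16% and 3.64% of calls. None of the 20 unchanged lists was called by camera, and the list that had been raised was called. Each gene was drawn on its own with no replicate effect. The simulations therefore leave out correlation between genes and cannot show how often it gives a false list call.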

Results

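Gene expression was measured on 24 arrays in BT-474, an established human breast cancer cell line with an amplified ERBB2 gene and an estrogen receptor. ERBB2 encodes the receptor tyrosine kinase HER2. The cells had received siRNA against HER2 or a control siRNA, and were treated with 10 nM estrogen or with vehicle (0.001% ethanol) for 4 or 24 h. These factors made 8 groups of 3 arrays each. The values were log2 RMA levels per probe set, 14335 genes were tested, and differences are given on the log2 scale as difference ± standard error. The number of arrays limits the precision. The median log2 level of an array ranged from 5.28 to 5.36, and arrays of 1 group correlated between 0.990 and 0.997. The series title names HER2 signalling, DNA synthesis and proliferation, and the comparisons below ask what HER2 siRNA and estrogen each changed and whether the estrogen response differed between the siRNAs.

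ERBB2, the targeted gene, was lower after HER2 siRNA in all 4 conditions. Averaged over the conditions its difference was -1.34 ± 0.06 (adjusted p = 1.11e-14, limma), which left 39.6% of the control level (95% confidence interval 36.5 to 42.9%). The difference was -1.56 ± 0.11 with vehicle at 4 h and -1.34 ± 0.11 with vehicle at 24 h, and -1.35 ± 0.11 with estrogen at 4 h and -1.09 ± 0.11 with estrogen at 24 h. With vehicle at 4 h the level was 13.66 ± 0.12 (SD, n = 3) with control siRNA and 12.10 ± 0.28 (SD, n = 3) with HER2 siRNA. The highest of the 12 HER2 siRNA arrays stood at 12.69 and the lowest of the 12 control siRNA arrays at 13.39. These values came from the brightest probe set of ERBB2, and its other probe sets differed by -1.47 ± 0.08 and -1.41 ± 0.10.

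**Figure D1:**
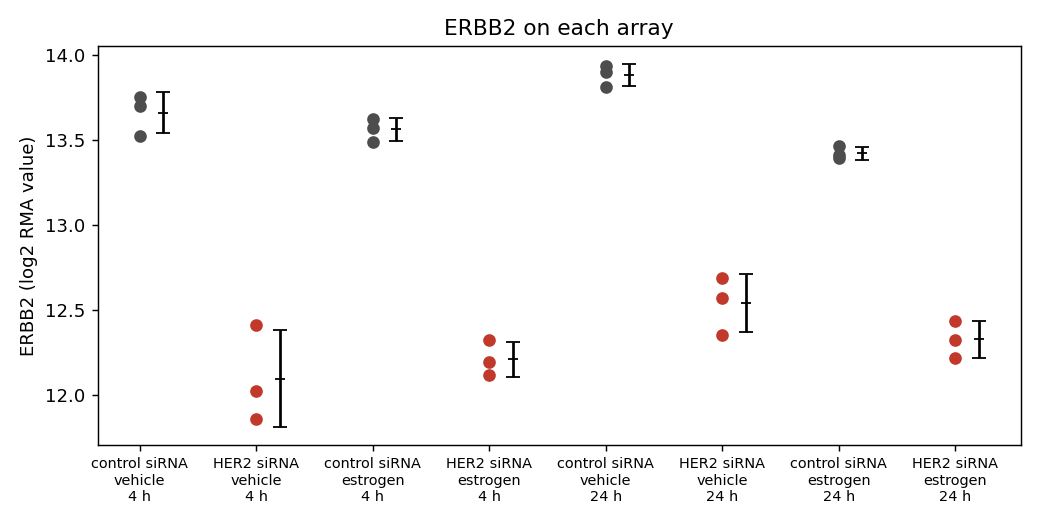
ERBB2 log2 RMA level (y axis) on each array of the 8 groups (x axis), with points for arrays and black bars for the group mean ± SD (n = 3). The 12 HER2 siRNA arrays lay at or below 12.69 and the 12 control siRNA arrays at or above 13.39.

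Genes of DNA synthesis and cell division were lower after HER2 siRNA. Averaged over the 4 conditions, 39 of 40 tested DNA replication genes fell (median -1.13), among them GINS2 (-1.80 ± 0.04) and MCM6 (-1.42 ± 0.04), parts of the replicative helicase, and RPA2 (-0.07) was the member that did not pass. All 35 mitosis genes fell (median -1.73), including the kinase CDK1 (-2.02 ± 0.07), the topoisomerase TOP2A (-2.01 ± 0.07) and the transcription factor FOXM1 (-1.70 ± 0.07). Of 29 nucleotide synthesis genes 23 fell and 2 rose, among them RRM2 (-2.14 ± 0.06), a subunit of ribonucleotide reductase, and TYMS, thymidylate synthase (-1.97 ± 0.07). RRM2 stood at 12.22 ± 0.08 with control siRNA and 9.92 ± 0.16 with HER2 siRNA (SD, n = 3) with vehicle at 4 h. Of 14 genes of DNA repair by recombination 13 fell, among them BRCA1 (-1.73 ± 0.07) and RAD51AP1 (-2.08 ± 0.07). Of 12 E2F and pocket protein genes 8 fell and 2 rose, with E2F7 (-2.70 ± 0.12) and E2F2 (-1.36 ± 0.06) among the falls. E2F1, which the series title names, was chosen after its values were seen and differed by -0.41. Of 15 G1 to S genes 9 fell, such as CCNE2, a cyclin (-1.70 ± 0.05), and 3 rose, such as the cyclin-dependent kinase inhibitor CDKN1C (1.74 ± 0.06). Each of these 6 lists was lower than the other genes by camera. The adjusted p was 5.40e-23 for replication, 4.61e-24 for mitosis, 8.02e-08 for nucleotide synthesis, 7.38e-09 for repair, 0.00843 for E2F and 0.0148 for G1 to S. With an estimated correlation the adjusted p was 0.0512 for mitosis, which ended that call. It was 0.0321, 0.0361, 0.0497, 0.0497 and 0.0497 for replication, nucleotide synthesis, repair, E2F and G1 to S. The E2F call ended with a stricter filter (adjusted p = 0.0622) and the G1 to S call when every probe set was tested (adjusted p = 0.135). The log2 difference between 3' and 5' GAPDH control probe sets, a sign of RNA integrity, moved with the siRNA too. It was 0.443 ± 0.060 (SD, n = 12) with HER2 siRNA and 0.305 ± 0.066 (SD, n = 12) with control siRNA (2-sided permutation p = 0.000110, adjusted p = 0.000220). The same measure of ACTB was 1.40 ± 0.333 and 1.17 ± 0.294 (2-sided permutation p = 0.0918).

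Lipid synthesis genes and genes downstream of MAPK signalling were also lower after HER2 siRNA, and FOXO-induced genes were higher, on the same arrays with the larger GAPDH 3' to 5' difference of 0.443. All 22 tested cholesterol and fatty acid synthesis genes fell (median -0.82, adjusted p = 7.38e-12, and 0.00100 with an estimated correlation), including the desaturase SCD (-1.23 ± 0.04) and the elongase ELOVL6 (-1.56 ± 0.06). For IDI1, an isomerase of the same list that counts as lower by its brightest probe set, 2 of 4 probe sets passed in the opposite direction. Of 15 MAPK pathway output genes 10 fell and 1 rose (adjusted p = 0.000815, and 0.0497 with an estimated correlation), and the feedback phosphatases DUSP4 (-1.59 ± 0.05) and DUSP6 (-1.64 ± 0.07) fell furthest with SPRED1 (-1.63 ± 0.10). Of 18 FOXO-induced genes 14 rose and 2 fell (median 0.89, adjusted p = 2.91e-06, but adjusted p = 0.103 with an estimated correlation). They included IRS2, an adaptor of the insulin receptor (2.29 ± 0.07), PIK3IP1, an inhibitor of phosphoinositide kinase signalling (1.85 ± 0.05), and KLHL24 (1.84 ± 0.08). Of 18 ribosome biogenesis genes 15 fell and 1 rose (median -0.23, adjusted p = 0.000376, but adjusted p = 0.114 with an estimated correlation), among them NOP16 (-0.59 ± 0.04) and RRS1 (-0.59 ± 0.05).

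Across all genes, 8490 of 14335 passed the threshold for the averaged HER2 siRNA effect, 4312 higher and 4178 lower, and 551 of them differed by at least 2-fold (218 higher, 333 lower). The largest rises were in KCNJ13, a potassium channel (2.95 ± 0.12), DYNLRB2, a dynein light chain (2.87 ± 0.08), N4BP2L1 (2.86 ± 0.17), PGM5 (2.82 ± 0.18) and DEPP1 (2.79 ± 0.14), and the ubiquitin ligase subunit FBXO32 rose by 2.33 ± 0.13. Next to E2F7, the largest falls were in DTL, a substrate receptor of a ubiquitin ligase (-2.57 ± 0.06), MCM10, a replication factor (-2.51 ± 0.12), SHCBP1 (-2.46 ± 0.10) and ZNF367 (-2.43 ± 0.08).

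The other lists were not called by camera for the averaged siRNA effect, and in all but the basal and mesenchymal list members passed in both directions. Fry, which does not weigh a list against the other genes, called some of them. It called the interferon list (fry adjusted p = 6.21e-07), basal and mesenchymal genes (1.3e-10) and neighbours of ERBB2 (0.0445) higher. The estrogen-induced list was lower by fry (adjusted p = 0.00213). Among 14 genes of the HER family and its ligands ERBB3 (0.96 ± 0.04) and ERBB4 (1.06 ± 0.08) rose while 5 members fell, ERBB2 included (4 rose in all, camera adjusted p = 0.911). Of 18 tested neighbours of ERBB2 in its chromosome region 8 rose and 6 fell (adjusted p = 0.792, median -0.004 and mean 0.10). FBXL20 differed by 0.81 ± 0.07 and PNMT by -0.82 ± 0.08. The falls include the kinase CDK12 (-0.59), for which 3 of 8 probe sets passed in the opposite direction and whose call ended with the mean of probe sets (adjusted p = 0.0542). Of 32 estrogen-induced genes 6 rose and 14 fell (adjusted p = 0.176), such as MYBL1 (-1.84 ± 0.14) and RET (-1.01 ± 0.09). In the interferon list, included as a sign of a transfection response, 9 of 17 rose and 1 fell (adjusted p = 0.0559). Both arms received siRNA, so this difference lies between the siRNAs and cannot show a response to transfection as such. HERC5 rose by 0.79 ± 0.07 on average, although its estrogen effect at 24 h differed between the siRNAs. Of 20 hypoxia and glycolysis genes 6 rose, such as KDM3A (0.89 ± 0.04), and 10 fell (adjusted p = 0.799, with the median at -0.14 and the mean at 0.01). Of 15 ATF4 and unfolded protein response genes 6 rose and 6 fell (adjusted p = 0.965, median 0.04 and mean -0.05), with PSAT1 at -1.21 ± 0.04. Of 10 nuclear receptor coregulators 2 rose and 3 fell (adjusted p = 0.911). Of 13 luminal genes 5 rose, such as GATA3 (0.53 ± 0.04), and 4 fell (adjusted p = 0.965). Of 4 tested basal and mesenchymal genes TWIST1 (1.67 ± 0.05) and VIM (0.29 ± 0.10) rose (adjusted p = 0.177). The median of that list was 0.22 and the mean 0.50, most of which came from TWIST1. Of 11 fibroblast, leukocyte and endothelial markers LYZ (1.08 ± 0.17) and COL1A1 (0.35 ± 0.07) rose and VWF (-0.32 ± 0.07) fell (adjusted p = 0.996, median -0.04 and mean 0.07). The calls of VIM and VWF ended with the GAPDH 3' to 5' difference as a covariate (adjusted p = 0.959 and 0.107), which was added after the array values were seen. Counted with p adjusted over the list alone, the numbers were the same in every list except nucleotide synthesis, where 3 rather than 2 rose.

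**Figure D2:**
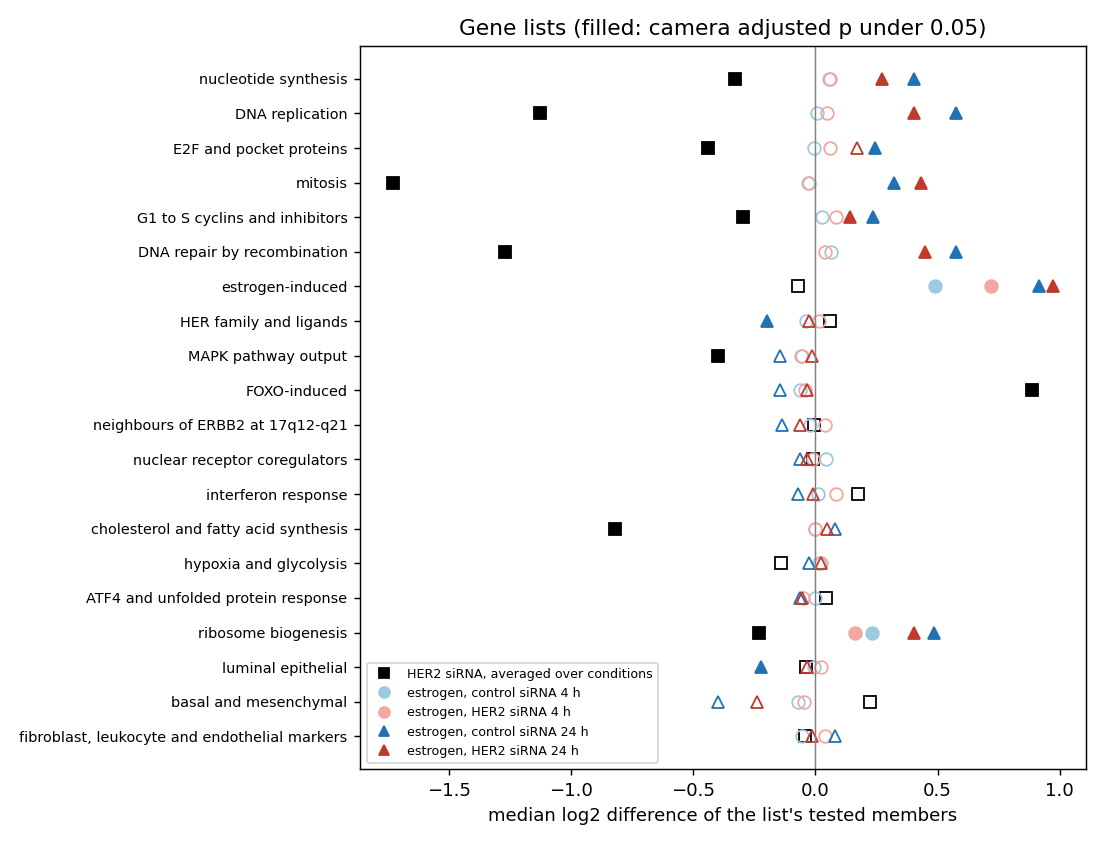
Median log2 difference of the tested members (x axis) of each of the 20 gene lists (y axis), with squares for the averaged HER2 siRNA effect, circles for estrogen at 4 h and triangles for estrogen at 24 h, blue for control siRNA and red for HER2 siRNA. Filled symbols had a camera adjusted p under 0.05, and DNA replication lay at -1.13 for HER2 siRNA and 0.57 for estrogen at 24 h with control siRNA.

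Within single conditions, genes of DNA replication and lipid synthesis were lower after HER2 siRNA in each of the 4, on arrays whose GAPDH 3' to 5' difference was the larger one of 0.443 on average. With vehicle at 4 and 24 h and estrogen at 4 and 24 h, 39, 38, 39 and 38 of 40 replication genes fell (40, 38, 39 and 38 adjusted over the list alone), with adjusted p = 0.00769, 0.0490, 0.00761 and 0.0183 with an estimated correlation. In the same order 18, 20, 17 and 20 of 22 cholesterol and fatty acid genes fell (19, 20, 18 and 22 adjusted over the list alone), with adjusted p = 0.00129, 0.000462, 0.00129 and 0.000291 with an estimated correlation. Camera at the preset correlation also called nucleotide synthesis, mitosis, repair, G1 to S, E2F, MAPK, FOXO-induced and ribosome lists in each condition. With vehicle at 24 h all of these ended with an estimated correlation (adjusted p = 0.0532, 0.0532, 0.0617, 0.0670, 0.0929, 0.0830, 0.0901 and 0.261). With an estimated correlation the FOXO-induced and ribosome calls also ended with vehicle at 4 h (adjusted p = 0.0689 and 0.171), estrogen at 4 h (adjusted p = 0.0817 and 0.0928) and estrogen at 24 h (adjusted p = 0.0712 and 0.125). With estrogen at 24 h the G1 to S and MAPK calls ended too (adjusted p = 0.0505 and 0.125 with an estimated correlation). The estrogen-induced list was called lower with vehicle at 4 h (adjusted p = 0.00832), and that call ended with an estimated correlation (adjusted p = 0.450).

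Single genes with large differences recurred. With vehicle, DEPP1 rose by 2.78 ± 0.29 at 4 h and 3.19 ± 0.29 at 24 h, and E2F7 differed by -2.62 ± 0.24 and -2.84 ± 0.24. With estrogen, KCNJ13 rose by 2.59 ± 0.24 at 4 h and 3.75 ± 0.24 at 24 h, and ZNF367 differed by -2.44 ± 0.15 and -2.40 ± 0.15. The counts past the threshold were 4909 with vehicle at 4 h (2361 higher, 2548 lower) and 5942 with vehicle at 24 h (2820 higher, 3122 lower). They were 4886 with estrogen at 4 h (2408 higher, 2478 lower) and 6019 with estrogen at 24 h (3080 higher, 2939 lower). Altogether 1524 genes were higher and 1747 lower in each of the 4. With equal medians, 55.0% and 54.4% of the genes past the threshold were higher with vehicle at 4 and 24 h. With estrogen at 4 and 24 h 54.3% and 51.7% were. Without that step the shares were 48.1%, 47.5%, 49.3% and 51.2% in the same order, so which direction led depended on the scaling. The vehicle effects at 4 and 24 h, measured on different arrays, shared 1751 higher genes where independent lists would share 464.5, and 2078 lower genes where they would share 554.9. Across genes, siRNA effects with vehicle and with estrogen, measured on different arrays, had a Pearson r of 0.926 at 4 h and 0.925 at 24 h. The r was 0.881 for vehicle at 4 h with estrogen at 24 h, and 0.880 for estrogen at 4 h with vehicle at 24 h.

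The HER2 siRNA effect differed between 4 and 24 h for 423 genes (248 with a higher difference at 24 h, 175 with a lower one). The siRNA difference of CYP1A1, a cytochrome, was higher by 1.93 at 24 h (adjusted p = 0.0201, limma). ALPP, placental alkaline phosphatase, had a siRNA difference higher by 1.75 ± 0.15 at 24 h and CAV1, caveolin, by 1.53 ± 0.26. In contrast, ANKRD22, GAS2L3, ASPM, a spindle protein (-0.96 ± 0.18), and DRAIC, a long noncoding RNA (-0.94 ± 0.13), fell further at 24 h. Of the 22 cholesterol and fatty acid genes 6 fell further at 24 h, 11 adjusted over the list alone (adjusted p = 1.40e-11, and 0.00105 with an estimated correlation). Of the 35 mitosis genes 12 fell further, 27 adjusted over the list alone, although that call (adjusted p = 6.30e-22) ended with an estimated correlation (adjusted p = 0.238). The calls of the FOXO-induced list (IRS2 and PDK4 past the threshold, 6 genes adjusted over the list alone, adjusted p = 0.00147), the MAPK list (DUSP6, and 3 genes adjusted over the list alone, adjusted p = 0.0110) and DNA replication (no member past the threshold, adjusted p = 0.0212), whose siRNA differences were higher at 24 h (medians 0.19, 0.19 and 0.10), also ended (adjusted p = 0.498, 0.238 and 0.999 with an estimated correlation). The count of 423 was 829 with the replicate number as a block. It was 261 without HER2 siRNA estrogen 24 h replicate 3, 262 without control siRNA vehicle 4 h replicate 2, 275 without HER2 siRNA vehicle 4 h replicate 1 and 278 without HER2 siRNA estrogen 24 h replicate 2.

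At 4 h, estrogen raised a small set of known estrogen-induced genes in cells with control siRNA. MYC rose by 2.30 ± 0.24, the transcription factor HEY2 by 2.03 ± 0.16, the trefoil peptide TFF1 by 1.34 ± 0.16 and the retinoic acid receptor RARA by 1.18 ± 0.10. MPPED2 rose by 2.67 ± 0.39 and PPM1K, a mitochondrial phosphatase, by 1.80 ± 0.23. Of 32 estrogen-induced genes 13 rose, 22 adjusted over the list alone (median 0.49, adjusted p = 1.01e-55, and 0.000286 with an estimated correlation). Of 18 ribosome biogenesis genes 5 rose, 9 adjusted over the list alone (adjusted p = 1.47e-21, and 0.000797 with an estimated correlation), such as RRS1 (0.54 ± 0.09). NOP16 rose by 0.65 ± 0.09, but its call ended with the mean of probe sets (adjusted p = 0.0896). The other 18 lists were not called by camera, and in DNA replication and mitosis no member passed. In all 48 genes rose and 1 fell, DKK1, an inhibitor of Wnt signalling (-0.38 ± 0.08), whose call ended when any 1 of the 6 arrays was left out (highest adjusted p 0.208). The count of 49 was 31 without control siRNA vehicle 4 h replicate 3, 30 without control siRNA estrogen 4 h replicate 2 and 27 without control siRNA estrogen 4 h replicate 3.

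At 24 h, estrogen raised the same list further in cells with control siRNA, together with DNA synthesis and ribosome genes. The vitamin carrier TCN1 rose by 4.00 ± 0.26, TFF1 by 3.34 ± 0.16, the amino acid transporter SLC6A14 by 3.48 ± 0.23, SUSD3 by 2.91 ± 0.14 and GREB1 by 2.94 ± 0.27, and PGR, the progesterone receptor, rose as well. Of 32 estrogen-induced genes 24 rose, 25 adjusted over the list alone (median 0.92, adjusted p = 4.37e-35). Of 40 DNA replication genes 34 rose, 36 adjusted over the list alone (median 0.57, adjusted p = 7.14e-31), such as MCM6 (0.81 ± 0.08) and RFC3 (0.89 ± 0.11). Of 29 nucleotide synthesis genes 19 rose, 22 adjusted over the list alone (adjusted p = 9.21e-17), such as IMPDH2 (0.73 ± 0.08) and PAICS (0.61 ± 0.07). Of 14 repair genes 10 rose, 11 adjusted over the list alone (adjusted p = 3.20e-10). Of 18 ribosome biogenesis genes 14 rose, all 18 adjusted over the list alone (adjusted p = 2.20e-18), such as FBL (0.60 ± 0.06). Of 15 G1 to S genes 7 rose and 1, CDKN1C, fell by 1.22 (8 and 2 adjusted over the list alone, adjusted p = 0.000837), and of 12 E2F and pocket protein genes E2F2, E2F4, E2F8 and TFDP1 rose (5 genes adjusted over the list alone, adjusted p = 0.00476). Without control siRNA vehicle 24 h replicate 1 or control siRNA estrogen 24 h replicate 2 the calls of E2F4, E2F8 and TFDP1 ended (highest adjusted p 0.0544, 0.0872 and 0.187). So did those of E2F8 and TFDP1 without control siRNA estrogen 24 h replicate 3, and that of TFDP1 without control siRNA vehicle 24 h replicate 2 or 3. The call of E2F2 ended without the 3 arrays numbered apart (adjusted p = 0.124). With an estimated correlation the adjusted p was 0.00129 for the estrogen-induced, nucleotide and ribosome lists, 0.00485 for replication, 0.00546 for G1 to S and 0.0308 for repair and E2F. Of 35 mitosis genes 9 rose, 13 adjusted over the list alone, including MAD2L1 (0.61 ± 0.12), but that call (adjusted p = 7.93e-09) ended with an estimated correlation (adjusted p = 0.267).

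Other genes were lower with estrogen at 24 h in cells with control siRNA. KCNJ13 fell, CBLN2 differed by -2.42 ± 0.23, PSCA, a surface antigen, by -1.39 ± 0.14 and SERPINI1, a protease inhibitor, by -1.38 ± 0.26. The HER family list was lower (adjusted p = 0.0131, and 0.0308 with an estimated correlation) with ERBB4 (-1.24 ± 0.15), EGFR (-0.59 ± 0.17) and ERBB2 (-0.46 ± 0.11, adjusted p = 0.00770) past the threshold, and TGFA (0.71 ± 0.15) went the other way. Adjusted over the list alone 5 fell and 1 rose. The calls of the list and of TGFA ended with the mean of probe sets (adjusted p = 0.0621 and 0.0923). That of EGFR ended with the mean of probe sets, with the GAPDH covariate and without the 3 arrays numbered apart (highest adjusted p 0.313), and without any 1 of the 6 arrays other than control siRNA estrogen 24 h replicate 2 (highest adjusted p 0.0945). Of 13 luminal genes 5 fell, 6 adjusted over the list alone, led by the transcription factors GATA3 (-0.95 ± 0.09), ELF3 (-0.64 ± 0.11) and FOXA1 (-0.40 ± 0.09), but the list's call (adjusted p = 0.00114) ended with an estimated correlation (adjusted p = 0.0628). The 10 other lists were not called by camera. In all 1939 genes passed, 1005 higher and 934 lower, and 1151 without the 3 arrays whose labels carry a separate number series. All 48 genes that rose at 4 h were among those that rose at 24 h, on different arrays, where independent lists would share 3.37.

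In cells with HER2 siRNA, estrogen raised 95 genes and lowered 5 at 4 h, and raised 613 and lowered 272 at 24 h. At 4 h MYC rose by 2.78 ± 0.24, RASGRP1, an activator of RAS, by 2.60 ± 0.32 and PMAIP1, a pro-apoptotic protein, by 2.09 ± 0.16. Of 32 estrogen-induced genes 20 rose, 26 adjusted over the list alone (adjusted p = 1.39e-58, and 0.000213 with an estimated correlation), and 2 of 18 ribosome genes rose (NOP16 and RRS1, 7 adjusted over the list alone, adjusted p = 2.39e-09, and 0.0368 with an estimated correlation). At 24 h TCN1 rose by 4.31 ± 0.26, RASGRP1 by 4.28 ± 0.32, TFF1 by 3.71 ± 0.16 and MYBL1 by 3.67 ± 0.29. Of the lists at 24 h, 26 of 32 estrogen-induced, 22 of 40 replication, 13 of 29 nucleotide and 11 of 18 ribosome genes rose (28, 29, 19 and 17 adjusted over the list alone), with adjusted p = 0.000313, 0.0181, 0.00246 and 0.00111 with an estimated correlation. The mitosis (10 of 35 higher, 22 adjusted over the list alone) and repair (8 of 14 higher, 10 and 1 lower adjusted over the list alone) calls ended with an estimated correlation (adjusted p = 0.203 and 0.0606). The G1 to S call (4 of 15 higher, 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.0181 with an estimated correlation) ended when every probe set was tested (adjusted p = 0.187). The genes shared with control siRNA, measured on different arrays, were 37 higher at 4 h, where independent lists would share 0.318, and 464 higher and 192 lower at 24 h, where they would share 43.0 and 17.7. The 4 h count of 100 was 64 without HER2 siRNA estrogen 4 h replicate 3, whose source name gives 24 h while its other labels give 4 h. With only the groups compared in the fit it was 28. The 24 h count of 885 was 551 and 587 without HER2 siRNA estrogen 24 h replicates 3 and 2 and 458 with only the groups compared.

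**Figure D3:**
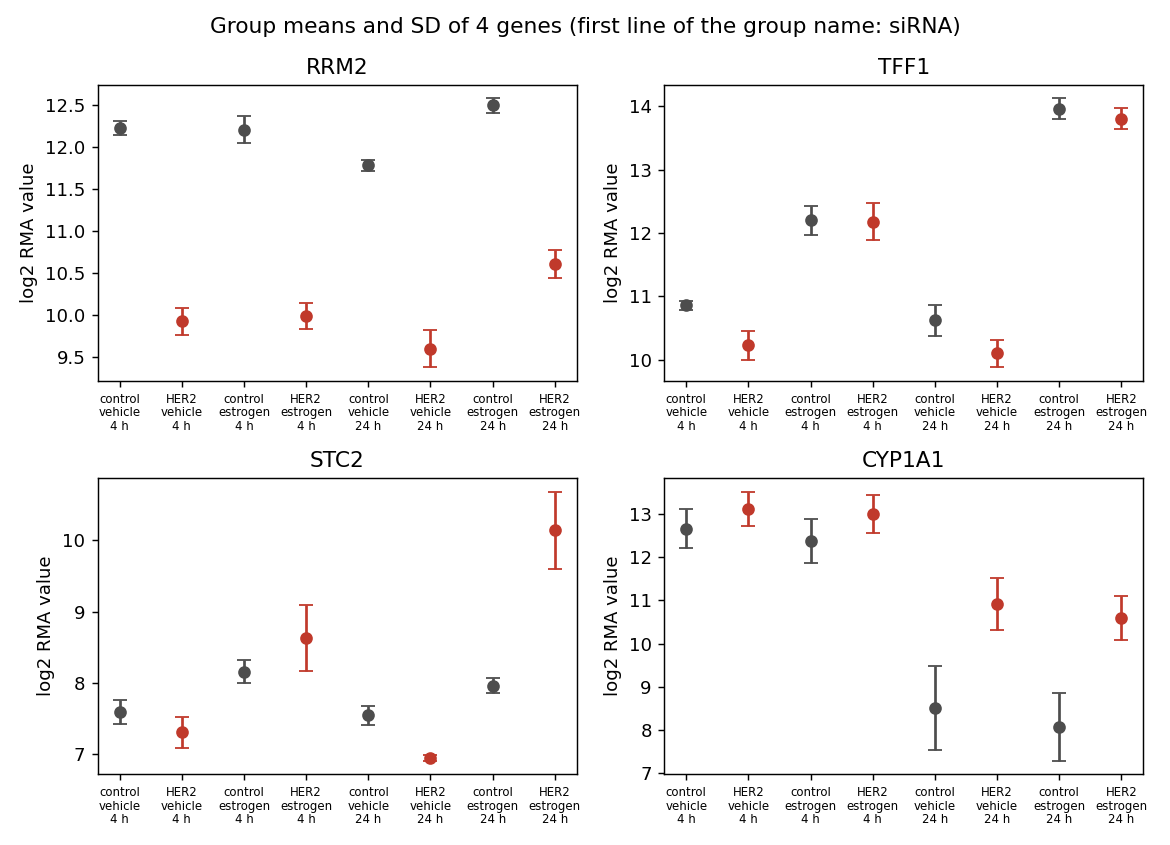
Group mean ± SD (n = 3) of the log2 RMA level (y axis) of RRM2, TFF1, STC2 and CYP1A1 in the 8 groups (x axis), grey for control siRNA and red for HER2 siRNA. STC2 with estrogen at 24 h stood at 7.96 with control siRNA and 10.14 with HER2 siRNA.

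The estrogen response itself differed between the siRNAs at 24 h for 9 genes, 7 with a higher and 2 with a lower estrogen effect in HER2 siRNA cells. STC2, a secreted glycoprotein hormone, went from 7.54 ± 0.13 with vehicle to 7.96 ± 0.10 with estrogen in control siRNA cells, and from 6.95 ± 0.04 to 10.14 ± 0.54 in HER2 siRNA cells (SD, n = 3). The difference of effects was 2.77 ± 0.29 (adjusted p = 7.66e-05, limma). The long noncoding RNA DSCAM-AS1 went from 7.61 ± 0.23 to 8.66 ± 0.12 and from 8.49 ± 0.25 to 11.07 ± 0.31, a difference of effects of 1.53 ± 0.21. HERC5, an interferon-induced ligase, differed by 1.67 ± 0.21 with 3 of its 4 group means at 24 h under the log2 level of 5 used as the filter, so that this size is approximate, and CELF2, an RNA-binding protein, by -1.26 ± 0.17. CDCA7L (-0.80 ± 0.12), KLK10 (1.39 ± 0.23), PCDH19 (1.18 ± 0.21), IRX2 (0.86 ± 0.15) and HBP1 (0.53 ± 0.10) made up the 9. Leaving out 1 of the 12 arrays ended the call of KLK10 without HER2 siRNA vehicle or estrogen 24 h replicate 2 (highest adjusted p 0.0616). It ended those of PCDH19, IRX2 and HBP1 in 7, 8 and 10 of 12 cases (highest adjusted p 0.103, 0.0959 and 0.154). The arrays at 24 h that did not end them were HER2 siRNA vehicle 1 and estrogen 1, control siRNA vehicle 1 and 2 and estrogen 3 for PCDH19. For IRX2 they were HER2 siRNA vehicle 3 and estrogen 1 and control siRNA vehicle 3 and estrogen 3, and for HBP1 HER2 siRNA vehicle 1 and control siRNA estrogen 1. With only the groups compared in the fit the calls of DSCAM-AS1 and CDCA7L ended as well (adjusted p = 0.0556 and 0.0787). No member of the DNA replication list passed (median -0.17, 1 lower adjusted over the list alone). Its camera call, with those of nucleotide synthesis, repair and the luminal list (adjusted p = 4.60e-10, 0.00983, 0.0413 and 0.0143), ended with an estimated correlation (adjusted p = 0.388, 0.388, 0.502 and 0.388). The count was 34 with the replicate number as a block, 4 with only the groups compared in the fit, and 17 and 5 without HER2 siRNA estrogen 24 h replicates 1 and 2.

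At 4 h no gene passed this test in limma, and 403 genes had an unadjusted p under 0.05. The estrogen-induced list was higher in HER2 siRNA cells by camera (median 0.20, adjusted p = 9.00e-07), with SUSD3 at 0.76 ± 0.19 and STC2 at 0.76 ± 0.29, neither past the threshold, and 1 member was higher adjusted over the list alone. That call ended with an estimated correlation (adjusted p = 0.968).

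The estrogen effect averaged over the siRNAs differed between 24 and 4 h for 500 genes, 302 with a higher and 198 with a lower effect at 24 h, and for 830 with the replicate number as a block. TCN1 (3.62 ± 0.26), the protease KLK11 (2.07 ± 0.18) and TFF1 (1.88 ± 0.16) rose more at 24 h, and CBLN2 (-1.47 ± 0.23), UBE2QL1 (-1.12 ± 0.12) and ERBB4 (-1.03 ± 0.15) had lower effects then. Of 40 DNA replication genes 28 had a higher effect at 24 h, 32 adjusted over the list alone (adjusted p = 2.21e-37, and 0.00392 with an estimated correlation). So did 11 of 29 nucleotide, 8 of 14 repair, 13 of 32 estrogen-induced and 4 of 18 ribosome genes (20, 11, 18 and 8 adjusted over the list alone, and adjusted p = 0.00190, 0.0201, 0.0104 and 0.0104 with an estimated correlation). The E2F list (1 higher, 3 adjusted over the list alone) and the G1 to S list (3 higher, 1 lower, 7 and 1 adjusted over the list alone) were called as well (adjusted p = 0.0409 and 0.0162 with an estimated correlation). The calls of mitosis (4 of 35 higher), cholesterol synthesis (no member past the threshold), the HER family (1 lower) and the luminal list (3 lower), with 20, 0, 3 and 6 past adjusted over the list alone, ended with an estimated correlation (adjusted p = 0.0803, 0.119, 0.0685 and 0.0510).

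In control siRNA cells with vehicle, 112 genes differed between 24 and 4 h (52 higher, 60 lower at 24 h), without estrogen or HER2 siRNA. This is no general background of time, since 926 genes differed in HER2 siRNA cells with vehicle, a comparison added after values were seen. With control siRNA the largest falls were in the xenobiotic-metabolising cytochromes CYP1A1 (-4.15 ± 0.44) and CYP1B1 (-3.46 ± 0.41). The death receptor FAS (-1.89 ± 0.40) and LCN2, a siderophore-binding protein (-1.27 ± 0.22), followed. The kinase SGK1 (0.76 ± 0.15) and the transcription factor MECOM (1.19 ± 0.23) were higher at 24 h. Leaving out 1 array ended the call of LCN2 in 3 cases (control siRNA vehicle 24 h replicates 1 and 3 and 4 h replicate 2, highest adjusted p 0.0663). It ended the call of FAS in all but 4 h replicates 2 and 3 (0.163), of SGK1 in all but 24 h replicate 1 and 4 h replicate 2 (0.123) and of MECOM in all but 4 h replicate 2 (0.120). DNA replication, nucleotide synthesis and the ATF4 list were lower by camera (adjusted p = 4.30e-11, 0.00693 and 2.85e-05, with 1, 0 and 0 members past the threshold and 11, 4 and 9 adjusted over the list alone). These calls ended with an estimated correlation (adjusted p = 0.286, 0.394 and 0.307). The count fell to 23, 29 and 6 without control siRNA vehicle 24 h replicates 1, 2 and 3 and to 9, 21 and 60 without 4 h replicates 1, 2 and 3, and rose to 448 with the replicate number as a block.

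Across genes, the averaged HER2 siRNA effect and the estrogen effect at 24 h averaged over the siRNAs were negatively related, with the same sign within each replicate number. The averaged estrogen effect, which called 1425 genes higher and 1240 lower, is a separate test from the effects within each siRNA. Of the genes called in both, 943 were lower after HER2 siRNA and higher with estrogen, where independent lists would share 415.3, and 715 were higher and lower, where they would share 373.0. Genes that moved the same way numbered 221 (higher) and 270 (lower), where 428.6 and 361.4 would be shared. The averaged effects had a Pearson r of -0.335 and a Spearman rho of -0.354 over 14335 genes. Within replicate numbers 1, 2 and 3 r was -0.309, -0.321 and -0.306 at 24 h and 0.0516, -0.106 and -0.0814 at 4 h. At 24 h r was -0.307 over the 14190 genes outside the 6 cell-division lists. Nearly all of the 14335 genes stay in that set, so this value cannot show whether the relation holds apart from cell division. At 4 h r was -0.0458 and rho -0.0800, and r turned positive without HER2 siRNA vehicle 4 h replicate 3 (0.0483) or HER2 siRNA estrogen 4 h replicate 1 (0.0417) and was -0.165 without HER2 siRNA vehicle 4 h replicate 1. Genes are not independent replicates. In 100 simulations of unchanged genes r ranged from -0.0330 to 0.0260 at 24 h and from -0.0348 to 0.0350 at 4 h, and these leave out correlation between genes. When estrogen and vehicle labels were permuted within siRNA, a reference added after the values were seen, r ranged from -0.349 to 0.367 at 24 h. Of 99 permutations, 6 at 24 h and 80 at 4 h lay as far from 0 as the observed r. These permutations set replicate numbers aside, and those that exchange estrogen and vehicle still hold the estrogen effect. Whether correlation between genes alone gives an r of this size was left open.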

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

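No test in this part was chosen after its result was seen. The estrogen effect at 24 h differed between the siRNAs for 9 genes by limma's interaction test. STC2, a secreted glycoprotein hormone, had an estrogen effect higher by 2.77 in HER2 siRNA cells, HERC5, an interferon-induced ligase, by about 1.67 with 3 of its 4 group means near background, and the noncoding RNA DSCAM-AS1 by 1.53. The effect was also higher in KLK10, a secreted protease, by 1.39, PCDH19, a protocadherin, by 1.18, the transcription factor IRX2 by 0.86 and the transcription factor HBP1 by 0.53. CELF2, an RNA-binding protein, differed by -1.26 and CDCA7L by -0.80. Of 100 splits of the arrays, the real one included, 19 gave 9 genes or more, and the highest other split gave 1204. Splits that exchange estrogen and vehicle within 1 siRNA turn the estrogen effect into a difference of effects, so counts of that size point to a structure of the samples. These splits hold the estrogen effect and are no measure of chance alone, and chance was not excluded by them, nor shown to give 9 genes. At 4 h limma called 0 genes (403 at an unadjusted p under 0.05). With a real count of 0 all 100 of 100 splits must give as many, so they say nothing about chance there, and the highest other gave 27.

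The HER2 siRNA effect differed between 4 and 24 h for 423 genes, with ALPP, placental alkaline phosphatase, and CAV1, caveolin, among those with a higher difference at 24 h. Only the real split of 100 gave as many genes, 1 of 100, and the highest other gave 189. Splits that exchange times within 1 siRNA hold the time effect, so they too are no measure of chance alone. The estrogen effect differed between the times for 500 genes, with TCN1 and TFF1 higher at 24 h and ERBB4 lower. Here too 1 of 100 splits, the real one, gave as many, and the highest other gave 25. For the averaged HER2 siRNA effect with its 8490 genes, DTL and E2F7 among the lower ones, 1 of 100 splits, the real one, gave as many. The highest other gave 11. All of these splits set replicate numbers aside and speak only for these arrays, which may not be separate cultures.

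For the 9 comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 5%. The real split was the 1 of 10 with the highest count in each. The real counts were 4909, 5942, 4886 and 6019 for HER2 siRNA with vehicle at 4 and 24 h and with estrogen at 4 and 24 h, 49 and 1939 for estrogen at 4 and 24 h with control siRNA, and 112 for time. The highest other split gave 0 in these. For estrogen with HER2 siRNA the real counts were 100 at 4 h and 885 at 24 h, and the highest other split gave 1 in both. In the comparisons whose numbers pair the arrays, the other splits that part all 3 pairs and those that part 1 pair gave no more than that.

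Among probe sets with no gene symbol or several, which no comparison of named genes used, 2912 passed the threshold for the averaged HER2 siRNA effect, 1920 higher and 992 lower of 6211 tested.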

How the results depend on the processing

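The test with the GAPDH 3' to 5' covariate was chosen after the values were seen. ERBB2 stayed past the threshold and lower for the averaged siRNA effect under each alternative run. The averaged count stayed between 8303 and 8472 when 1 array was left out. Signal over background limits genes near a log2 level of 5, such as HERC5. List tests of the siRNA effect within single conditions were run with the preset and the estimated correlation and fry, and not under the other alternatives. For the values below the cause was not tested unless given.

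With the replicate block the counts were 76 and 153 for estrogen at 4 h with control and HER2 siRNA, 34 for the interaction at 24 h, 829 for siRNA by time, 830 for estrogen by time and 448 for time. With the block and the number series they were 75 for estrogen with control siRNA at 4 h, 29 for the interaction, 768 for siRNA by time and 400 for time. With array weights they were 81, 22, 725, 771 and 379 for estrogen with control siRNA at 4 h, the interaction at 24 h, siRNA by time, estrogen by time and time. With them 4 and 3 lists were called for estrogen with HER2 siRNA at 4 h and the interaction at 4 h. A trend and robust prior gave 16 for the interaction at 24 h. With only the groups compared, which leaves fewer arrays for the spread, the counts were 28 and 458 for estrogen with HER2 siRNA at 4 and 24 h, 4 for the interaction and 43 for time. Without the 3 arrays numbered apart they were 1151 for estrogen with control siRNA at 24 h and 43 for time, with 4 lists called for estrogen with HER2 siRNA at 4 h and 3 for siRNA by time.

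Testing every probe set gave 15121 for the averaged siRNA effect, 7815 and 10073 with vehicle at 4 and 24 h, 7973 and 10103 with estrogen, and 173 for time, since more features were tested. For the interaction at 24 h 7 lists were then called, 7 with the mean of probe sets and 2 with no filter. With the mean of probe sets the estrogen effect at 24 h with control siRNA turned in CDK12 (-0.000564, adjusted p = 0.997) and HK2 (0.218, adjusted p = 0.0609). The stricter filter gave 187 for time. With an estimated correlation 0 lists were called for the interaction at 4 h and 0 at 24 h, 1 for siRNA by time and 7 for estrogen by time, and fry called 0 and 0 for the interactions. For the averaged siRNA effect fry kept the mitosis, FOXO-induced and ribosome calls (fry adjusted p = 8.96e-14, 1.82e-12 and 5.40e-10), without weighing them against other genes. The relation across genes at 24 h was -0.325 with no filter, -0.355 with the stricter filter, -0.345 with the mean of probe sets, -0.322 with every probe set and -0.352 with the GAPDH 3' to 5' covariate.

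Leaving out 1 array gave counts of 27 to 46 for estrogen with control siRNA at 4 h, 64 to 95 and 551 to 796 with HER2 siRNA at 4 and 24 h. They were 5 to 17 for the interaction at 24 h, 261 to 495 for siRNA by time and 6 to 60 for time. Lists called ranged from 2 to 6 and 2 to 5 for estrogen at 4 h with control and HER2 siRNA, and from 1 to 4 and 1 to 5 for the interactions at 4 and 24 h. The relation ranged from -0.357 to -0.304 at 24 h and from -0.165 to 0.0483 at 4 h. The mitosis median ranged from -0.12 to 0.16 for estrogen with HER2 siRNA at 4 h and from -0.13 to 0.18 for the interaction at 4 h.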

Other observations

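Of the tests in this part, the covariate on the GAPDH 3' to 5' difference and the comparison of CYP1A1 in the other 3 pairs of groups were chosen after the result was seen. The hypoxia and glycolysis list, which was not called for HER2 siRNA, had members past the threshold in both directions, and the examples here were chosen after their values were seen. Among the falls were LDHA, lactate dehydrogenase, at -0.77 ± 0.05, PDK1, a kinase of pyruvate dehydrogenase, at -0.59 ± 0.07, ALDOA, an aldolase, at -0.41 ± 0.04 and PGK1 at -0.40 ± 0.03. Among the rises were NDRG1 (0.96 ± 0.05), ANKRD37 (0.67 ± 0.04), ADM (0.60 ± 0.09) and BNIP3 (0.59 ± 0.03). With 24 h of estrogen in control siRNA cells NDRG1 (-0.70 ± 0.10) and DDIT4 (-0.76 ± 0.11) fell, and the glucose transporter SLC2A1 rose (0.69 ± 0.17).

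The cytochromes CYP1A1 and CYP1B1 and TIPARP were lower at 24 h than at 4 h in each of the 4 conditions, and CYP1A2 passed the threshold with control siRNA vehicle alone (adjusted p = 0.0471, and 0.0609, 0.169 and 0.211 in the others). That call ended when any 1 of the 6 arrays was left out (highest adjusted p 0.247) and under 8 other alternatives. CYP1A1 differed by -4.15 ± 0.44, -4.31 ± 0.44, -2.19 ± 0.44 and -2.40 ± 0.44 with control siRNA vehicle, control siRNA estrogen, HER2 siRNA vehicle and HER2 siRNA estrogen. In that order CYP1B1 differed by -3.46 ± 0.41, -2.60 ± 0.41, -3.38 ± 0.41 and -2.53 ± 0.41, and TIPARP, a target of the aryl hydrocarbon receptor, by -1.01 ± 0.23, -0.82 ± 0.23, -0.96 ± 0.23 and -0.78 ± 0.23. The counts past the threshold for time were 112, 855, 926 and 890 in the same order. For CYP1A1 the siRNA effect differed between the times by 1.93 (adjusted p = 0.0201, limma), with the smaller falls in HER2 siRNA cells.

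DNA replication and mitosis genes were lower after HER2 siRNA, with a median of -1.43 over the 75 members, and the GAPDH 3' to 5' difference was larger on the same arrays. With that difference as a covariate the median was -1.38, with 73 rather than 74 members lower past the threshold, and without the arrays numbered apart it was -1.46, so neither accounts for the pattern as a whole. The siRNA itself, which the design names, stays open as the biological explanation. An effect of this siRNA on other transcripts may also contribute and was not tested, since no other HER2 siRNA was used here.

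CYP1A1 was lower at 24 h than at 4 h in control siRNA cells with vehicle. Its difference closest to 0 was -3.72 when 1 array or the arrays numbered apart were left out, and -2.19 in the other 3 pairs of groups, so neither single arrays nor those 2 groups alone account for it. A candidate explanation is higher activity of the aryl hydrocarbon receptor at 4 h. With control siRNA vehicle its target genes not seen before had a median of -0.35, with 4 of 4 tested genes lower and none past the threshold. AHRR differed by -0.53 ± 0.16 and NQO1 by -0.49 ± 0.23. ALDH3A1 (-0.21 ± 0.16) and GSTA1 (-0.16 ± 0.19) lay near the log2 level of 5 used as the filter. Their direction therefore carries little weight. All 4 had negative differences with control siRNA estrogen too, but those of ALDH3A1 (-0.06 ± 0.16) and GSTA1 (-0.05 ± 0.19) were smaller than their standard errors. With HER2 siRNA the 4 genes went both ways. AHRR was lower with HER2 siRNA vehicle (-0.56, adjusted p = 0.0385), but ALDH3A1 (0.16) and GSTA1 (0.09) were positive there. GSTA1 (0.33) was also positive with HER2 siRNA estrogen, and none of these 3 positive differences passed the threshold.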
